A study of Mus musculus with 10 samples.

How the data were processed

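Poly(A) RNA (500 ng per library, Kapa mRNA HyperPrep, HiSeq3000) was sequenced from 10 libraries of cultured mouse CD8+ T cells in 5 groups of 2. The deposited tables hold, for each library, read counts per RefSeq transcript as the authors counted them, together with RPKM that the authors computed from those counts, the transcript length and a library total of 45138204 to 62848913 reads. According to the submitters' notes, reads were aligned to mm10 with TopHat2 (given as 2.2.1) and Bowtie2 2.2.6, and SAMtools 0.1.8, bedtools 2.25.0 and edgeR, with no version, were used. The strand setting is not given in the sources used here. A read that falls on several transcripts of 1 gene was counted in each of them.

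The tables list 31682 transcripts of 23992 symbols, of which 4343 have several transcripts. For each symbol the transcript with the most reads over all libraries was kept. No transcript of the mitochondrial chromosome is listed, so 1 of 32 gene lists, that of mitochondrially encoded genes, could not be tested. The kept transcripts held 27137191 to 46656183 reads per library, with 15978 to 17259 genes at 1 read or more, and the most abundant gene took 1.16 to 1.68% of them. The lowest depth was that of IL-21 replicate 2, where 59.9% of the authors' total fell on kept transcripts. Of the kept transcripts 23642 were found in a RefSeq table, 23528 of them on the chromosome the files give. Coordinates are those of mm10.

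Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and a robust quasi-likelihood fit over the 10 libraries, with 14357 genes tested and a common biological coefficient of variation of 0.171. There were 7 comparisons, the last an interaction. All tests are two-sided, p values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and genes at an adjusted p below 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. The gene lists (658 members in all) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, 31 lists in each comparison and 217 tests in all, adjusted within a comparison. Camera with an estimated correlation and fry were run beside it. Of the 217 tests 109 were called, 48 upward and 61 downward, and 40 kept the call with an estimated correlation. The median, the mean and the test differed in sign in 23, 0 of which camera called. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

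Where a gene had 0 reads in a group, its fold change is a lower bound against a floor of 3 counts over the group, and with 1 to 3 reads a ratio with a 95% counting interval applies. Intervals and floors cover counting error only. Principal components used the 1000 most variable genes. The groups, comparisons, lists, named genes and alternatives were chosen before the data were examined, except where stated. Genes named are the 6 with the largest change in each direction of a comparison (called, replicates of the groups not overlapping, mean RPKM of at least 5 in the higher group, no predicted, immunoglobulin or T cell receptor gene), up to 4 members per list by p, and 16 fixed genes, 1 of which is not reported here. Cd8a, Cd3e, Mcpt8 and Cd79a, where outside that rule, and the macrophage and basophil genes plotted were chosen after their values were seen.

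The alternatives tried were RLE size factors, library size alone, DESeq2 1.42.0, no filter on low genes, a filter of RPKM 5 in 2 samples, limma on log2(RPKM + 1), a fit of only the groups compared, the replicate number as a block, a minimum of 1.5-fold and 10 fits that each leave out 1 library. The longest transcript of each gene, a GC trend taken out of each library, and list tests without 1 library or with library size alone were added after seeing the data.

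The test was tested on simulated data of 14039 genes, with the same spread of a gene in all groups. The measured spread was wider in IL-21 (SD of the log2 difference between replicates 0.805) than in IL-2 + LDHi (0.355). The rates below may thus be too favourable for comparisons with IL-21. For IL-21 + LDHi against IL-21, 13.6% of genes changed 1.5-fold, 51.6% of those changed 2-fold and 89.1% of those changed 4-fold were called, with 5 false among 104 calls. For the interaction these were 1.5, 18.8 and 79.7%, with 9 false among 73 calls. Tests for outlying samples and regroupings of samples need larger groups than 2 and were left out.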

Results

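Activated CD8+ T cells can turn into short-lived killer cells or keep features of longer-lived memory cells, and both the cytokine they receive and their metabolism steer that choice. The series asked what the cytokines IL-2 and IL-21, each with or without a block of lactate dehydrogenase (LDH, the enzyme that turns pyruvate into lactate at the end of glycolysis), do to the RNA of such cells. CD8+ T cells from the spleens of C57BL/6N mice were activated through CD3 and CD28 for 48 h and then kept for 48 h without cytokine, with IL-2 (100 IU/ml) or with IL-21 (100 ng/ml). In a further pair of groups the LDH inhibitor NCI-737 (LDHi, 1 µM), a compound known by its code name, was present from activation onward together with IL-2 or IL-21. No group received the inhibitor without a cytokine, and effects on activation cannot be told apart from effects on the response to the cytokine. Each of the 5 groups had 2 poly(A) RNA libraries. Fold changes are log2 values ± SE and levels are mean RPKM ± SD, with n = 2 libraries per group. The p values measure only the spread between these libraries, which may be technical, since the labels do not say what the replicate number stands for.

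The IL-2, IL-2 + LDHi and IL-21 + LDHi libraries each lay apart by group on the first pair of principal components, while the IL-21 libraries and those without cytokine lay next to each other. On the first principal component of the 1000 most variable genes (43.6% of their variance) the IL-21 + LDHi libraries lay at 64.6 and 60.4, the libraries without cytokine at -54.0 and -70.4, and the IL-21 libraries at -33.4 and -48.3. On the second (40.5%) the IL-2 libraries lay at 79.0 and 75.5, those without cytokine at -20.4 and -26.1, and the IL-21 libraries at -11.6 and -16.0. On these axes IL-21 replicate 2 lay closer to no cytokine replicate 1 than to IL-21 replicate 1. The fourth component (3.78%) set these groups apart, with the IL-21 libraries at -24.9 and -21.5 and those without cytokine at 15.6 and 20.2. Replicates correlated across genes with r between 0.969 in IL-21 and 0.995 in IL-2 + LDHi. Genes that mark CD8+ T cells were not called as a list, though single members were. Of 12 identity genes, Cd3e, a chain of the T cell receptor complex, measured 194 ± 39.7 RPKM without cytokine, 171 ± 4.81 in IL-2 and 195 ± 3.63 in IL-21 + LDHi, and Cd8a measured 248 ± 28.8, 192 ± 18.7 and 206.3 ± 6.45. The median changes of the list lay between -0.34 and 0.18 over the 7 comparisons. Of its members 4 were lower with the inhibitor in IL-21, 2 higher and 3 lower with it in IL-2, and 4 higher and 1 lower in IL-21 against IL-2, and the lowest interaction among them was -1.06. Cd3e and Cd8a were picked after their values were seen.

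**Figure D1:**
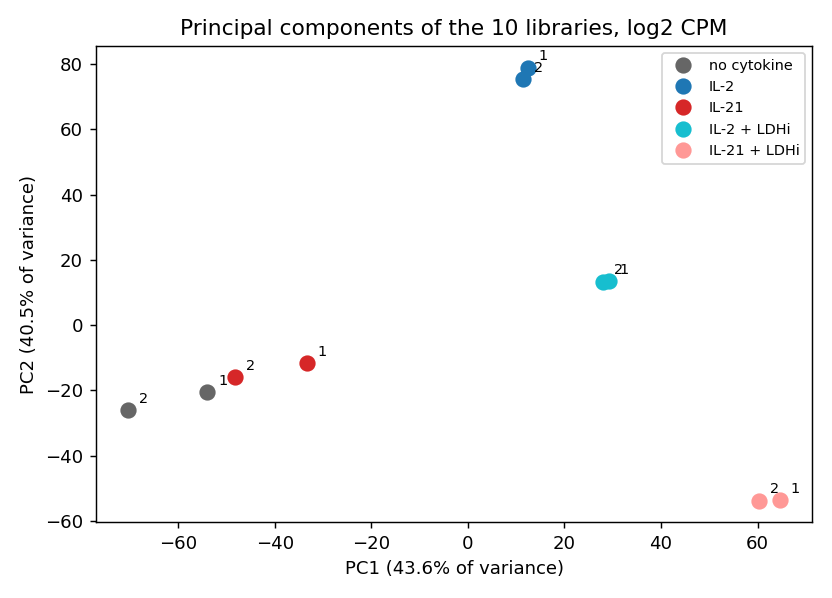
Principal components of the 10 libraries from the log2 CPM of the 1000 most variable genes, the first on the x axis and the second on the y axis, each point 1 library with its replicate number. The IL-2 libraries lie apart on the second component (79.0 and 75.5) and the IL-21 + LDHi libraries at the opposite corner (first component 64.6 and 60.4).

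The first question was what IL-2 adds to activated cells. With IL-2, the lists of cytotoxic molecules, glycolysis and division were called higher and that of stem, memory and naive genes lower. With an estimated correlation the cytotoxic (adjusted p = 0.168), glycolysis (0.0747), S phase (0.0874) and stem calls (0.0747) were lost. Gzmb, which encodes the granule protease granzyme B (chromosome 14, 56258836 to 56262334, mm10), rose by 5.92 ± 0.29 (adjusted p = 3.01e-06), from 17.8 ± 6.29 to 1088 ± 85.3 RPKM. Il2ra, the alpha chain of the IL-2 receptor, rose by 4.65 ± 0.37, Tnfrsf9, the costimulatory receptor 4-1BB, by 4.87 ± 0.18, and Cish, a feedback inhibitor of cytokine signalling, by 4.16 ± 0.26. Ldha, which encodes the muscle-type LDH subunit (chromosome 7, 46842274 to 46855627), rose by 2.17 ± 0.17 (adjusted p = 2.03e-05), from 214.5 ± 8.18 to 977 ± 122 RPKM, while no difference was detectable for Ldhb, the heart-type subunit (0.46 ± 0.24, adjusted p = 0.135). Tcf7, which encodes the memory and stem cell factor TCF-1, fell by 1.38 ± 0.16 (adjusted p = 0.000151) and Il7r, the receptor for a survival cytokine, by 1.09 ± 0.18. Prf1, which encodes perforin, fell by 0.62 ± 0.11 (adjusted p = 0.00154), against the direction of Gzmb. In the stem, memory and naive list 21 of 26 genes were lower and 2 higher (median -1.16), among them Il6ra lower by -4.15 ± 0.22 and Bcl2 higher by 2.78 ± 0.17.

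Several metabolic lists were higher with IL-2. Glycolysis genes were higher in 21 of 25 and lower in 1 (median 2.09), with Aldoc, an aldolase, up by 6.39 ± 0.26 and Hk2, the hexokinase of the first step, up by 2.81 ± 0.31. Of 25 HIF-1 targets outside glycolysis 21 were higher (median 2.45, for example P4ha2, a collagen hydroxylase, 6.75 ± 0.42). ATF4 and stress response genes were higher in 26 of 32 (median 2.00, Asns, which makes asparagine, 3.96 ± 0.16), cholesterol genes in 23 of 23 (median 2.16, Fdps 3.06 ± 0.17) and fatty acid synthesis genes in 13 of 15 (median 1.31, Scd2 3.96 ± 0.16). Of TCA cycle genes 15 of 25 were higher (median 0.44, camera adjusted p = 0.00135; 0.206 with an estimated correlation) and of nuclear-encoded respiratory chain genes 27 of 53 (median 0.43, 0.00108; 0.591). G2 and M phase genes were higher in 25 of 25 (median 2.19), S phase genes in 25 of 27 (median 1.47), and IL-2 and STAT5 targets in 18 of 20 (median 1.99). Of cytotoxic molecules 13 of 21 were higher and 4 lower, and of effector transcription factors 10 of 16 were higher and 2 lower (Nfil3 3.89 ± 0.17), and both calls were lost with an estimated correlation (adjusted p = 0.168 and 0.056). Adjusted over the list alone, 22 glycolysis, 22 HIF-1 and 28 ATF4 genes were higher. Camera called the G2 and M (adjusted p = 5.92e-39; 0.026 with an estimated correlation), ATF4 (3.17e-18; 0.00993), cholesterol (1.08e-25; 0.0219), fatty acid synthesis (2.11e-08; 0.0219) and STAT5 lists (5.59e-16; 0.00993). The calls of glycolysis (4.84e-24), HIF-1 (7.37e-18), S phase (2.23e-19), stem (5.32e-10), effector factor (2.08e-06) and cytotoxic lists (0.00135) were made only with the preset correlation (0.0874 for HIF-1 with an estimated one). Of 35 interferon-stimulated genes 15 were lower and 3 higher (adjusted p = 0.0497; 0.483 with an estimated correlation). That call also ended without IL-2 replicate 1 (0.103), IL-21 replicate 1 (0.0779), no cytokine replicate 2 (0.069) or IL-21 replicate 2 (0.0788). The fatty acid oxidation list (7 of 17 higher, adjusted p = 0.0886) was not called. Of 14357 genes tested by edgeR's quasi-likelihood test, 7247 differed, 3681 higher and 3566 lower, and 1927 and 1931 of these by at least 2-fold.

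The second question was what IL-21 adds. The lists of cytotoxic molecules and STAT3 targets were called higher, and the glycolysis list was not called. Gzmb rose by 5.43 ± 0.28 (adjusted p = 1.81e-05) to 682 ± 14.4 RPKM, Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445894), by 4.33 ± 0.27 (4.6e-05) to 22.0 ± 5.07 RPKM, and Prf1 by 1.64 ± 0.11 (6.41e-05) from 11.1 ± 1.11 to 31.1 ± 3.19 RPKM. Socs3, a STAT3-induced feedback inhibitor, rose by 3.56 ± 0.17 (1.03e-05), Bcl3 by 3.20 ± 0.17 and the receptor gene Il21r by 1.57 ± 0.13. Cytotoxic molecules were higher in 14 of 21 (median 1.26, camera adjusted p = 5.29e-25; 0.0123 with an estimated correlation) and STAT3 targets in 8 of 16 (median 0.38, 1.76e-12; 0.0123). Pim1, a survival kinase, rose by 1.90 ± 0.11 and Cd38 by 1.67 ± 0.19. In the heat shock and immediate early list 4 of 16 genes were higher and none lower (1.47e-06; 0.0271), led by Jun (3.38 ± 0.16), and in fatty acid synthesis 6 were higher and 1 lower of 15 (4.29e-05; 0.0484), led by Elovl6 (2.44 ± 0.11). G2 and M genes (16 of 25 higher, median 0.64, 1.76e-12), S phase genes (5 of 27 higher, 1.2e-05), MYC and ribosome biogenesis genes (12 of 26 higher and 1 lower, 9.88e-08), inhibitory receptors (8 of 18 higher and 4 lower, 0.00423) and cholesterol genes (5 of 23 higher, 3.18e-05) were called, and these calls were lost with an estimated correlation (adjusted p = 0.102, 0.343, 0.102, 0.102 and 0.194). Effector factors (4 higher and 2 lower of 16, 0.000421; 0.112 with an estimated correlation) were called too. Adjusted over the list alone, 21 G2 and M, 19 MYC and 13 cholesterol genes were higher. The glycolysis (2 higher and 2 lower of 25, median 0.08, adjusted p = 0.412) and stem lists (3 higher and 4 lower of 26, 0.412) were not called. No difference was detectable for Tcf7 (0.33 ± 0.16, adjusted p = 0.215), Ccr7 (-0.05 ± 0.22, 0.914) or Ldha (0.53 ± 0.17, 0.0762).

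The IL-21 pair had the widest spread of the replicate pairs (SD of the log2 difference 0.805). The count of 1658 called genes (811 higher, 847 lower, 342 and 434 of them by at least 2-fold) came to 1104 without IL-2 replicate 1, 1093 without IL-2 replicate 2, 3921 without IL-21 replicate 1, 954 and 946 without IL-2 + LDHi replicates 1 and 2, and 756 without no cytokine replicate 2. Fitting only the 2 groups compared gave 105 calls, so the spread shared by all groups may be too small for this comparison. The fit of only 2 groups ended the calls of Bcl6, a memory-associated repressor (1.29 ± 0.13, adjusted p = 0.000536), and Pdcd1, which encodes PD-1 (1.99 ± 0.25, 0.00198). The STAT5 target list (4 of 20 higher and 1 lower, adjusted p = 0.00961; 0.137 with an estimated correlation) lost its call without no cytokine replicate 2 (0.118). The list of nuclear and noncoding RNAs meant as a check of RNA quality (1 of 9 higher, Miat by 5.31 ± 0.56; 0.00937, and 0.194 with an estimated correlation) lost it without IL-21 replicate 2.

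Set directly against IL-2, most genes of the glycolysis, stress response and division lists were lower in IL-21 and most stem genes higher, and of these lists only that of the stress response kept its call with an estimated correlation. Tcf7 (chromosome 11, 52246527 to 52283383) was higher by 1.71 ± 0.16 (adjusted p = 6.5e-05), at 581 ± 97.1 against 199 ± 19.2 RPKM, and Bcl6 by 1.87 ± 0.13 (1.41e-05). Prf1 was higher by 2.27 ± 0.11 and Ifng by 2.67 ± 0.24, while no difference was detectable for Gzmb (-0.49 ± 0.23, adjusted p = 0.109) or Pdcd1 (0.07 ± 0.24, 0.818). Ldha was lower by -1.65 ± 0.17, Ldhb by -1.23 ± 0.24 and Hk2 by -2.91 ± 0.31. Glycolysis genes were lower in 24 of 25 (median -1.94, camera adjusted p = 1.24e-25), HIF-1 targets in 22 of 25 (-2.32, 3e-17), cholesterol genes in 23 of 23 (-1.74, 5.8e-20) and G2 and M genes in 25 of 25 (-1.59, 1.24e-25), and stem genes were higher in 19 of 26 and lower in 3 (0.93, 2.22e-09). These calls were lost with an estimated correlation (adjusted p = 0.0587, 0.0964, 0.0587, 0.0587 and 0.0587). The ATF4 list (27 of 32 lower, median -1.85, 7.62e-21; 0.0118) and STAT5 targets (14 of 20 lower and 1 higher, -2.09, 3.75e-13; 0.0243) kept theirs. Lta, a lymphotoxin, was lower by -4.58 ± 0.17, whereas STAT3 targets (8 of 16 higher and 2 lower, 0.000475; 0.0587 with an estimated correlation) were led by Socs3 (3.95 ± 0.17). Cytotoxic molecules (8 of 21 higher and 3 lower, 0.0476; 0.36) lost their call without IL-2 replicate 1 (0.0563), IL-2 replicate 2 (0.064) or IL-21 replicate 2 (0.0817). Effector factors (9 lower and 4 higher of 16, 0.00151; 0.119), S phase genes (23 of 27 lower, 3.75e-13; 0.119), fatty acid synthesis genes (11 lower and 1 higher of 15, 0.00026; 0.0587), TCA genes (11 of 25 lower, 0.00454; 0.249) and chemokine receptor and adhesion genes (12 higher and 4 lower of 23, 0.00393; 0.0587) were called only with the preset correlation. So were respiratory chain genes (16 of 53 lower, 0.0108; 0.655), not called without IL-21 replicate 2 (0.203), and interferon-stimulated genes (14 higher and 7 lower of 35, 0.0141; 0.387), not called without IL-2 replicate 1 (0.0563). In all 7123 genes differed, 3580 higher and 3543 lower in IL-21, 1882 and 1908 of them by at least 2-fold, and 4592 did so without IL-2 replicate 1. The 2 cytokine responses shared 483 genes higher and 502 lower, against 207.9 and 210.4 for independent lists. Changes correlated across genes (r = 0.405, rho = 0.335), with the caution that genes are not independent replicates. Both responses use the same libraries without cytokine. Simulated unchanged groups against shared controls gave a mean r of 0.497, which holds for groups without effects and cannot be set against the measured r. Their mean covariance over 20 draws was 0.0849, against 0.502 measured. Part of the overlap may come from the shared controls. Genes of other blood cells were highest without cytokine, and the myeloid and dendritic list had medians of -4.12 with IL-2 and -1.30 with IL-21. Part of the genes lower in both may thus lie in other cells, a difference the simulation did not hold. Shared higher genes came to 302 without IL-2 replicate 1, 852 without IL-21 replicate 1, 308 and 307 without IL-2 + LDHi replicates 1 and 2, and 249 without no cytokine replicate 2. Shared lower genes came to 280 and 271 without IL-2 replicates 1 and 2, 947 and 802 without IL-21 replicates 1 and 2, 278 and 272 without IL-2 + LDHi replicates 1 and 2, and 179 without no cytokine replicate 2.

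The third question was what LDH inhibition changes in cells kept in IL-2. Most genes called both for IL-2 and for the inhibitor moved in opposite directions, metabolic and effector genes among them. Ldha, the target's own gene, fell by 1.85 ± 0.17 (adjusted p = 8.44e-05) to 280 ± 9.77 RPKM, Hk2 by 2.86 ± 0.31 and Aldoc by 6.63 ± 0.26. Gzmb fell by 3.67 ± 0.26 (2.04e-05) to 88.1 ± 6.62 RPKM, which is still above the 17.8 ± 6.29 RPKM without cytokine. Lag3 and Ctla4, inhibitory receptors, fell by 4.33 ± 0.34 and 3.73 ± 0.23, Pdcd1 by 1.92 ± 0.25 and Prdm1, which encodes the effector factor Blimp-1, by 1.67 ± 0.18. Il6ra rose by 4.46 ± 0.22, Itgae, the integrin CD103, by 3.80 ± 0.18 (from 1.49 ± 0.0631 to 21.3 ± 0.741 RPKM), and Prf1 by 0.74 ± 0.11. Glycolysis genes were lower in 24 of 25 (median -1.94, camera adjusted p = 7.47e-30; 0.0423 with an estimated correlation), cholesterol genes in 23 of 23 (-1.82, 8.77e-28; 0.0246), ATF4 genes in 29 of 32 (-1.75, 7.31e-24; 0.0132), fatty acid synthesis genes in 13 of 15 (-0.85, 9.75e-11; 0.0224), effector factors in 12 of 16 with 1 higher (-1.24, 4.72e-12; 0.0246), inhibitory receptors in 12 of 18 with 3 higher (-1.34, 1.93e-05; 0.0282) and STAT5 targets in 11 of 20 (-1.29, 3.28e-08; 0.0272). HIF-1 targets (23 of 25 lower, -2.30, 8.65e-25), stem genes (14 of 26 higher and 2 lower, 0.58, 7.88e-10), G2 and M genes (17 of 25 lower, -0.56, 0.000193) and cytotoxic molecules (7 of 21 lower and 2 higher, 0.00278) lost their calls with an estimated correlation (adjusted p = 0.0524, 0.0547, 0.298 and 0.206). Adjusted over the list alone, 18 stem genes were higher and 19 G2 and M genes lower. S phase genes (7 lower and 1 higher of 27, adjusted p = 0.536), p53 targets (7 lower and 3 higher of 18, 0.131), fatty acid oxidation genes (8 of 17 lower, 0.0605), TCA genes (6 of 25 lower, 0.179) and respiratory chain genes (8 lower and 1 higher of 53, 0.481) were not called. MYC and ribosome biogenesis genes (15 higher and 2 lower of 26, 0.000798; 0.206) and chemokine receptor and adhesion genes (6 higher and 2 lower of 23, 0.0213; 0.119) were called only with the preset correlation. Mki67, a proliferation marker, measured 116 ± 0.777 RPKM with and 131 ± 10.5 RPKM without the inhibitor.

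Some memory genes sat close to the limit of that comparison. Tcf7 rose by 0.60 ± 0.16 (adjusted p = 0.0162), a call that ended without IL-2 replicate 1 or either IL-2 + LDHi library, with values from 0.51 to 0.71. Il7r rose by 0.61 ± 0.18 (0.0229), a call that ended without any 1 of the 4 libraries compared (0.51 to 0.70). No difference was detectable for Ccr7, a lymph node homing receptor (0.05 ± 0.22, 0.869) or Ifng (0.10 ± 0.24, 0.767). In all 5657 genes differed, 2557 higher and 3100 lower, 923 and 1745 of them by at least 2-fold. The count came to 3423 and 3725 without IL-2 replicates 1 and 2, and to 3226 and 3248 without IL-2 + LDHi replicates 1 and 2. Fitting only those 2 groups gave 9101. Of 4339 genes called both here and for IL-2 against no cytokine, 4216 (97.2%) moved in opposite directions. Their changes correlated across genes with r = -0.672 and rho = -0.733. In 20 simulated unchanged sets sharing the IL-2 libraries the mean r was -0.497, which again holds only without effects. The covariance of -1.43 lay below the lowest of those sets, -0.0854, but the sets held no IL-2 effect. IL-2 enters the comparisons with opposite signs, so genes set apart by IL-2 alone would also give a negative covariance.

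**Figure D2:**
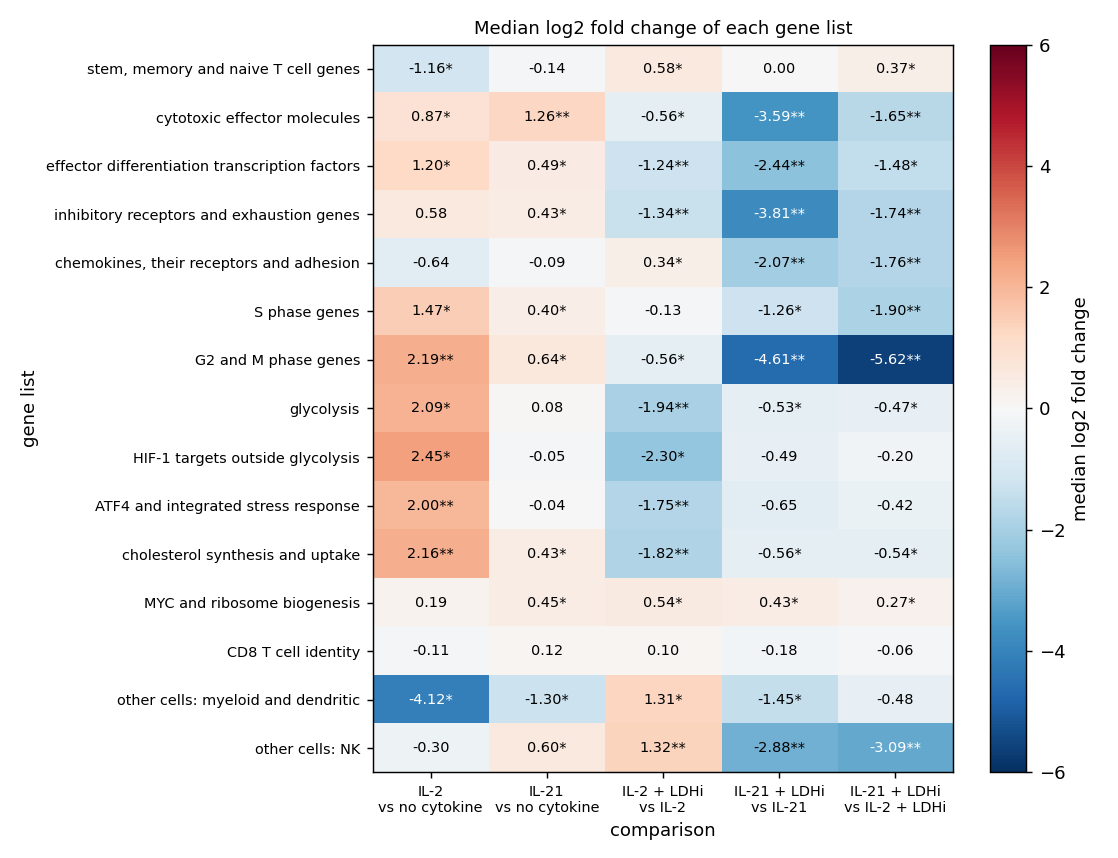
Median log2 fold change (colour and number) of the tested genes of 15 fixed lists (y axis) in 5 comparisons (x axis), with genes at 0 counts in a group set at their bound. A star marks a camera call and a second star a call kept with an estimated correlation, for example -1.94 for glycolysis in IL-2 + LDHi against IL-2 and -4.61 for G2 and M phase genes in IL-21 + LDHi against IL-21.

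The fourth question was what LDH inhibition changes in cells kept in IL-21. G2 and M genes, cytotoxic molecules and effector factors fell. Gzmb fell by 8.51 ± 0.33 (adjusted p = 4.46e-07) to 1.93 ± 0.402 RPKM, below the level without cytokine. Ifng fell by 5.82 ± 0.30 (1.98e-06) to 0.394 ± 0.160 RPKM, Pdcd1 by 3.82 ± 0.28 (1.57e-05), Prdm1 by 2.65 ± 0.20 and the activating receptor gene Klrk1 by 5.51 ± 0.18. Prf1 did not change detectably (-0.10 ± 0.11, adjusted p = 0.517), at 29.8 ± 1.60 RPKM. Mki67 (chromosome 7, 135689784 to 135716450) fell by 5.31 ± 0.17 (3.5e-07), from 50.8 ± 0.530 to 1.32 ± 0.105 RPKM. Ccr7 rose by 1.63 ± 0.22 (adjusted p = 0.000614), from 107 ± 48.3 to 329 ± 6.80 RPKM, while no difference was detectable for Tcf7 (-0.02 ± 0.16, 0.932), which stayed at 583 ± 15.1 RPKM. Igfbp4, an insulin-like growth factor binding protein, rose by 3.28 ± 0.18 to 1122 ± 33.3 RPKM and Ampd1, a muscle AMP deaminase, by 3.50 ± 0.21. G2 and M genes were lower in 25 of 25 (median -4.61, camera adjusted p = 9.2e-125; 0.00346 with an estimated correlation), cytotoxic molecules in 20 of 21 (-4.03, or -3.59 with genes at 0 counts set at their bound, 1.6e-27; 0.00638), inhibitory receptors in 15 of 18 with 2 higher (-3.81, 1.56e-15; 0.00461), effector factors in 14 of 16 (-2.44, 2.9e-15; 0.0147) and chemokine receptor and adhesion genes in 16 of 23 with 1 higher (-2.07, 1.32e-10; 0.00638). In the last list Cd44, an adhesion receptor of activated cells, fell by 3.38 ± 0.14 and Cxcr3, which guides T cells to inflamed tissue, by 3.87 ± 0.29. S phase genes (21 of 27 lower, median -1.26, 3.79e-18) and STAT5 targets (11 of 20 lower and 2 higher, 0.000344) lost their calls with an estimated correlation (adjusted p = 0.0968 and 0.075). The glycolysis list was lower in 13 of 25 and higher in 1 (median -0.53, 0.0225; 0.625 with an estimated correlation), and not called without IL-21 replicate 1 (0.259). Hk2 fell by 2.69 ± 0.33. MYC and ribosome biogenesis genes were higher in 15 of 26 (median 0.43, 8.82e-06; 0.128 with an estimated correlation).

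The respiratory chain (53 genes, adjusted p = 0.308) and TCA cycle lists (4 higher and 1 lower of 25, 0.224) were not called in the IL-21 comparison. Cholesterol genes (14 of 23 lower, 0.00464; 0.401), fatty acid synthesis genes (7 of 15 lower, 0.00912; 0.101) and interferon-stimulated genes (15 lower and 1 higher of 35, 0.00464; 0.401) were called only with the preset correlation. The stem list was not called: 8 genes were higher and 7 lower of 26 (median 0.00, mean 0.14, adjusted p = 0.0517). Its members went both ways: Dapl1, a marker of naive and memory cells, rose by 1.79 ± 0.11, Bcl2 by 1.89 ± 0.17 and the cytokine receptor chain Il6st by 1.68 ± 0.12, while the costimulatory receptor gene Cd28 fell by 2.15 ± 0.20. Egr2 and Egr1, early genes of receptor signalling, fell by 3.89 ± 0.26 and 4.38 ± 0.32. The heat shock and immediate early list (6 of 16 lower and 2 higher, 0.0347; 0.142 with an estimated correlation) lost its call without IL-21 replicate 1 (0.103), no cytokine replicates 1 and 2 (0.0535 and 0.0537) or IL-21 + LDHi replicate 2 (0.0506). Ldhb rose by 1.67 ± 0.24 (adjusted p = 0.000952). Ldha fell by 0.70 ± 0.17 (0.0125), a call that ended without either IL-21 + LDHi library (-0.92 to -0.43). Socs3 rose by 0.52 ± 0.15 (0.0278), a call that ended without either IL-2 library, IL-21 replicate 2 or IL-21 + LDHi replicate 2 (0.35 to 0.72). The LDH family list of 3 tested genes was not called in any comparison, with adjusted p = 0.308 here. Of 974 genes called both for the inhibitor in IL-21 and for IL-21 against no cytokine, 497 (51%) moved in opposite directions, against 97.2% for IL-2. In all 4501 genes differed, 1589 higher and 2912 lower, 333 and 2144 of them by at least 2-fold. Without IL-21 + LDHi replicate 1 the count was 2659 and without replicate 2 it was 2522.

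**Figure D3:**
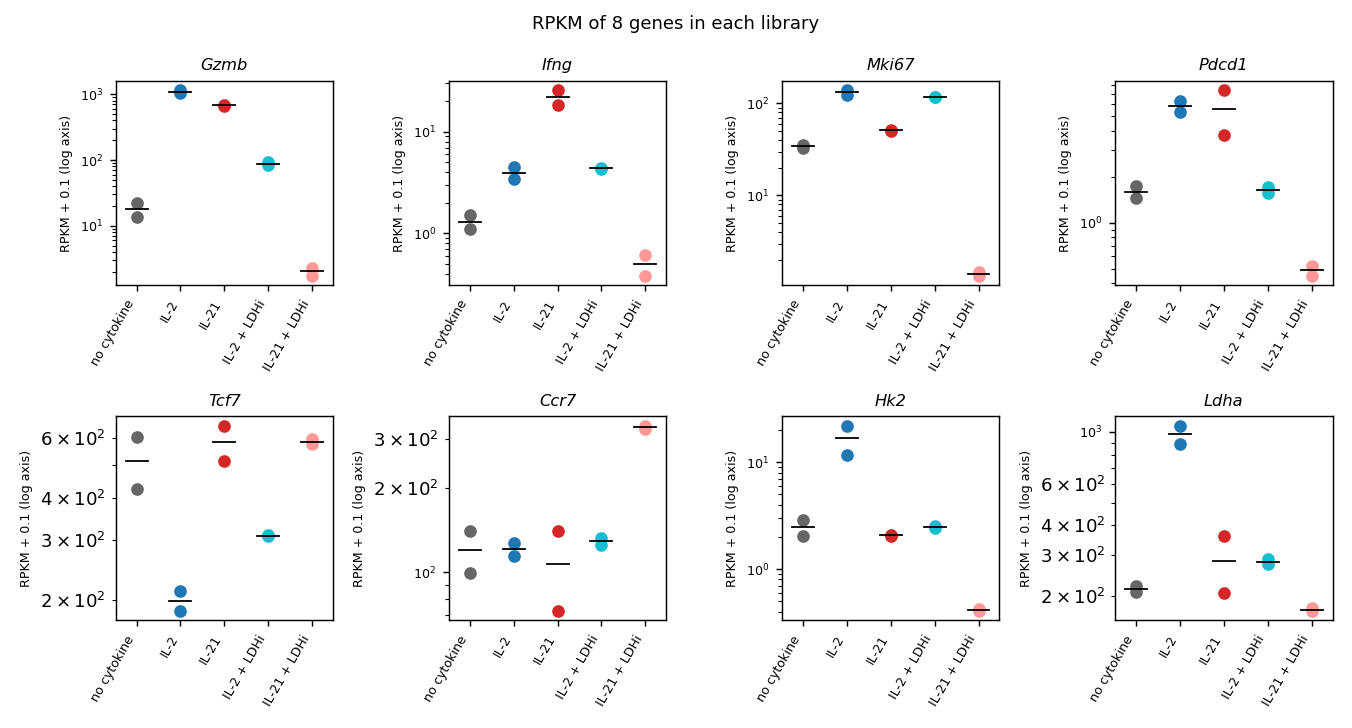
RPKM plus 0.1 (log y axis) of 8 genes in the 5 groups (x axis), each point 1 library and each line the mean of 2. In IL-21 + LDHi Gzmb averages 1.93 RPKM and Mki67 1.32 RPKM, the lowest of the groups, while Ccr7 averages 329 RPKM, the highest.

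Compared with each other under the inhibitor, IL-21 cells held fewer division transcripts than IL-2 cells, while genes of the stem list differed both ways. Mki67 was lower by -6.28 ± 0.17 (adjusted p = 7.56e-08), Gzmb by -5.33 ± 0.29 and Ifng by -3.25 ± 0.28. Tcf7 was higher by 1.10 ± 0.16 (0.000961), Ccr7 by 1.54 ± 0.22 (0.000873), Bcl6 by 2.60 ± 0.14, Prf1 by 1.43 ± 0.11 and Socs3 by 3.78 ± 0.17. Moxd1, a monooxygenase-like gene with 34.3 ± 3.23 RPKM in IL-21 + LDHi and listed at 0 in IL-2 + LDHi, was at least 3920-fold higher. No difference was detectable for Ldha (-0.50 ± 0.17, adjusted p = 0.0563), Ldhb (-0.01 ± 0.23, 0.989) or Il7r (-0.35 ± 0.17, 0.179). G2 and M genes were lower in 25 of 25 (median -5.62, camera adjusted p = 6.04e-170; 0.00237 with an estimated correlation), S phase genes in 26 of 27 (-1.90, 1.54e-48; 0.0289), cytotoxic molecules in 11 of 21 with 1 higher (6.22e-09; 0.0289), and STAT5 targets in 11 of 20 with 2 higher (8.84e-08; 0.0288). Inhibitory receptors (12 lower and 2 higher of 18, 1.23e-05; 0.0289) and chemokine receptor and adhesion genes (15 lower and 2 higher of 23, 1.11e-07; 0.0288) were lower as well. STAT3 targets were higher in 7 of 16 and lower in 4 (0.000267; 0.0289). Effector factors (10 lower and 2 higher of 16, 1.1e-05; 0.0671) and MYC genes (7 of 26 higher, 0.0193; 0.387) were called only with the preset correlation. Stem genes (11 higher and 8 lower of 26, median 0.37, 0.0152), ER chaperones (10 of 20 lower, 0.00548, Xbp1 by -1.39 ± 0.12), pentose phosphate and NRF2 genes (8 of 18 lower and 1 higher, 0.0159, Txn1 by -1.97 ± 0.17), glycolysis genes (12 of 25 lower, 0.00717) and cholesterol genes (14 of 23 lower, 0.0274) lost their calls with an estimated correlation (adjusted p = 0.387, 0.383, 0.387, 0.583 and 0.501), the last also without IL-2 + LDHi replicate 2 (0.0681). In all 3742 genes differed, 1348 higher and 2394 lower, 419 and 1583 of them by at least 2-fold. The count was 2149 and 2098 without IL-2 + LDHi replicates 1 and 2, 2254 and 2207 without IL-21 + LDHi replicates 1 and 2, and 7404 with only these 2 groups fitted.

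Whether LDH inhibition acts alike under both cytokines was tested as an interaction, the inhibitor's effect in IL-21 minus that in IL-2. The effect was lower in IL-21 than in IL-2 for the lists of G2 and M genes and cytotoxic molecules, and higher for that of ATF4 genes. A difference between the effects does not mean that a list fell under both cytokines. The calls of other metabolic lists were lost with an estimated correlation. Mki67 differed by -5.10 ± 0.21 (adjusted p = 5.39e-06), Ifng by -5.92 ± 0.38 (1.64e-05), Gzmb by -4.84 ± 0.36 (4e-05) and Itgae by -5.21 ± 0.25 (5.99e-06). Aldoc differed by 4.64 ± 0.37 (6.32e-05), Bnip3, a HIF-1 target, by 4.62 ± 0.36, and Ccr7 by 1.58 ± 0.31 (0.00672). No difference between the effects was detectable for Tcf7 (-0.62 ± 0.22, 0.0816) or Hk2 (0.16 ± 0.44, 0.829). G2 and M genes were lower in 25 of 25 (median -3.79, camera adjusted p = 2.55e-104; 0.00286 with an estimated correlation), chemokine receptor and adhesion genes in 16 of 23 (-2.53, 7.05e-18; 0.00286) and cytotoxic molecules in 15 of 21 (-2.72, 7.05e-18; 0.0115), and ATF4 genes were higher in 18 of 32 (1.31, 3.63e-12; 0.0115). Glycolysis genes (20 of 25 higher, median 1.41, 1.9e-17), HIF-1 targets (17 of 25 higher and 1 lower, 2.19, 8.09e-17) and stem genes (14 of 26 lower and 4 higher, -0.89, 0.000346) lost their calls with an estimated correlation (adjusted p = 0.0878, 0.0878 and 0.221). So did cholesterol genes (17 of 23 higher, 1.47e-13; 0.0585), fatty acid synthesis genes (8 higher and 1 lower of 15, 0.000145; 0.0515) and S phase genes (17 lower and 1 higher of 27, 1.59e-15; 0.0878), while inhibitory receptors (11 of 18 lower, 1.54e-05; 0.0256) kept theirs. Adjusted over the list alone, 21 glycolysis genes were higher and 17 stem genes lower. TCA genes (3 of 25 higher, 0.00973; 0.347 with an estimated correlation) lost theirs without IL-21 replicate 2 (0.0688). Prdm1 differed by -0.98 ± 0.26 (0.0279), a call that ended without IL-2 replicate 2 or any 1 of the 4 inhibitor libraries (-1.18 to -0.83), and turned to 0.13 by limma on log2(RPKM + 1).

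In all 3124 genes had a different inhibitor effect, 1146 higher and 1978 lower, 703 and 1484 of them by at least 2-fold. The count was 1950 and 1996 without IL-2 replicates 1 and 2, 5170 without IL-21 replicate 1, 1780 and 1830 without IL-2 + LDHi replicates 1 and 2, and 1989 and 1951 without IL-21 + LDHi replicates 1 and 2. The effects also had a common part: 784 genes were higher and 1352 lower with the inhibitor under both cytokines, against 283 and 629 for independent lists, among them Ctla4 and Asns lower and Dapl1 higher. Of 2497 genes called under both, 361 (14.5%) moved in opposite directions. The changes correlated across genes with r = 0.327 and rho = 0.364, and these comparisons share no library (mean r 0.001 in simulated unchanged sets). The count of 784 came to 433 and 518 without IL-2 replicates 1 and 2, 1242 without IL-21 replicate 1, 410 and 394 without IL-2 + LDHi replicates 1 and 2, and 375 and 327 without IL-21 + LDHi replicates 1 and 2. The count of 1352 came to 853 and 859 without IL-2 + LDHi replicates 1 and 2.

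Transcripts of other blood cells were present and differed between groups. Lyz2, the lysozyme of macrophages and neutrophils, measured 131 ± 25.4 RPKM without cytokine, 34.6 ± 1.68 in IL-21, 8.67 ± 3.60 in IL-2 + LDHi, 2.94 ± 1.24 in IL-21 + LDHi and 1.38 ± 0.385 in IL-2. Mcpt8, a basophil protease, measured 195 ± 87.8, 43.4 ± 1.39, 0.150 ± 0.00230, 0.179 ± 0.150 and 1.24 ± 0.0512 RPKM in the same order. C1qb, a macrophage complement gene, was listed at 0 in IL-2 and at least 282-fold lower than without cytokine. Of 21 myeloid and dendritic genes 17 were lower in IL-2 than without cytokine (median -4.12, camera adjusted p = 3.42e-12; 0.0874 with an estimated correlation), 8 lower in IL-21 than without cytokine (-1.30, 1.26e-05; 0.194), 16 higher and 1 lower in IL-21 than in IL-2 (3.91, 8.57e-09; 0.116), 11 higher and 2 lower with the inhibitor in IL-2 (1.31, 0.000798; 0.298) and 14 lower with it in IL-21 (-1.45, 0.000426; 0.352). In the interaction 12 were lower (-4.68, 7.05e-10; 0.0968). Of 10 natural killer cell genes, several of which activated CD8+ T cells also express, 7 were higher with the inhibitor in IL-2 (1.32, 0.000103; 0.0423) and 9 lower with it in IL-21 (-2.88, 8.82e-06; 0.0375), among the latter Klre1 (-5.07 ± 0.29). Of the same list 3 were higher and 1 lower in IL-21 than without cytokine (0.00651; 0.102), 5 higher in IL-21 than in IL-2 (0.00128; 0.0587), 9 lower and 1 higher in IL-21 + LDHi than in IL-2 + LDHi (2.76e-05; 0.0289), and 10 of 10 lower in the interaction (2.98e-15; 0.00544). Of 7 CD4+ and regulatory T cell genes 6 were lower in IL-21 + LDHi than in IL-2 + LDHi (-3.19, 4.87e-05; 0.0289) and 5 lower in IL-21 than in IL-2 (0.0168; 0.116). B cell (3 of 12 lower, median -3.24, camera adjusted p = 0.0638) and erythroid genes (1 of 8 lower, median -1.30, 0.221) were not called in IL-2 against no cytokine. With these medians, the missing calls do not show equal levels. The B cell list had a lower median in replicate 2 than in replicate 1 of all 5 groups (by 0.31 in IL-2 to 2.21 in IL-21 + LDHi), so its test carries a spread that goes with the replicate number. Of the nuclear and noncoding RNAs listed as a check of RNA quality, 5 of 9 were higher in IL-21 + LDHi against IL-2 + LDHi (median 1.06, 0.00332; 0.169 with an estimated correlation). Whether they track quality or a change in the cells was not tested.

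**Figure D4:**
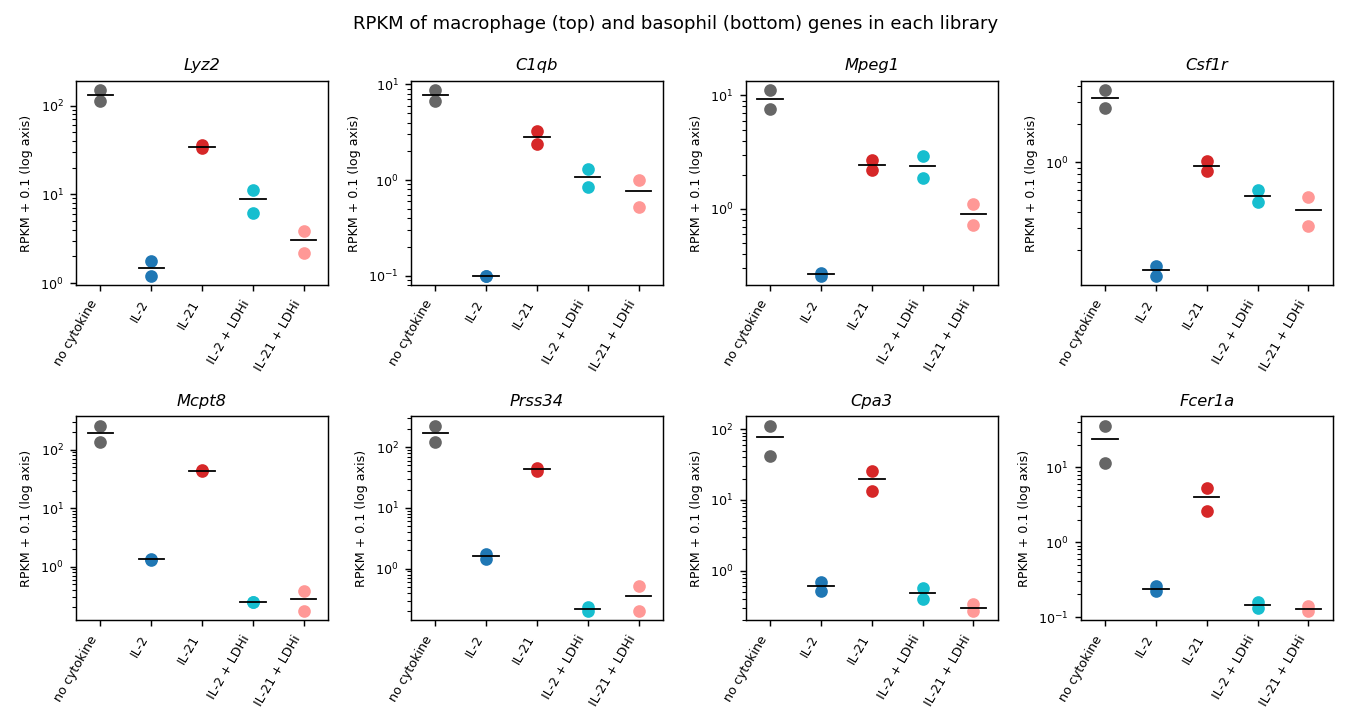
RPKM plus 0.1 (log y axis) of 4 macrophage genes (top) and 4 basophil genes (bottom) in the 5 groups (x axis), each point 1 library and each line the mean of 2. Both sets are highest without cytokine (Lyz2 131 and Mcpt8 195 RPKM), and Mcpt8 is near 0 in the inhibitor groups (0.150 and 0.179 RPKM).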

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

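The tests of a single mixture of other cells (in all groups and in 2 of them), of overall library scale, of transcript length and of the size of the GC trend were chosen after the result was seen, and the remaining ones before. What singles out the results below is that the inhibitor's effect differed between IL-21 and IL-2 by a test of the interaction itself (edgeR, adjusted p below the threshold). That held for 3124 genes. Among the largest, Fam183b differed by 7.61 (log2, effect in IL-21 minus effect in IL-2), Moxd1 by 6.83, Mgarp by 6.10, Ak4 by 6.02, Neb by 5.91 and Dnm1 by 5.56, and Gzmc by -7.80, Mpo by -7.64, Itgax by -7.13, Ctsg by -7.07, Prg2 by -6.48 and Gzma by -6.48. For 5 of these the fitted value depends on groups with 0 to 3 reads and is no measured size. Moxd1 had 0 reads in IL-2 + LDHi and 2 in IL-2, so no fold is given in IL-2. Fam183b had 1 read in IL-2 + LDHi, 664-fold (counting interval 119 to 26200) below IL-2, and 3 and 1 in the IL-21 groups. With the inhibitor in IL-21, Gzmc was 407-fold (113 to 3360), Ctsg 338-fold (116 to 1640) and Prg2 254-fold (70.4 to 2100) lower, from 2 to 3 reads. Mpo, Ctsg and Prg2 are genes of granulocytes or other myeloid cells. Itgax changed with the inhibitor by 0.75 in IL-2 and -6.38 in IL-21, near Gzma (0.52 and -5.96), and is not assigned to a cell type here. Of 21 myeloid and dendritic genes 12 had a lower interaction (median -4.68, camera adjusted p = 7.05e-10; 0.0968 with an estimated correlation). Among the fixed genes Ldha differed by 1.15, Ldhb by 1.22, Ccr7 by 1.58, Il7r by -0.89, Gzmb by -4.84, Prf1 by -0.84, Ifng by -5.92, Prdm1 by -0.98, Bcl6 by 0.73, Pdcd1 by -1.90 and Slc2a1 by 1.41.

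The directions within each cytokine differ by gene. Gzmb (-3.67 in IL-2 and -8.51 in IL-21), Pdcd1 (-1.92 and -3.82) and Prdm1 (-1.67 and -2.65) were lower with the inhibitor under both and more so in IL-21. Ldha (-1.85 and -0.70) and Dnm1 (-7.75 and -2.19) were lower by more in IL-2. Ak4 was lower in IL-2 (-6.94), with no difference detectable in IL-21 (-0.92, edgeR adjusted p = 0.271). Neb was lower with the inhibitor in IL-2 (-3.72) and higher in IL-21. Several of these calls rest on single libraries. The call of Fam183b ended without either no cytokine library, either IL-2 library, IL-2 + LDHi replicate 2 or IL-21 + LDHi replicate 2 (5.16 to 9.73), that of Moxd1 without either IL-2 library (6.74 to 6.94), that of Mgarp without IL-2 replicate 1 or any inhibitor library (5.16 to 7.21), and that of Dnm1 without IL-21 + LDHi replicate 2 (5.04 to 6.05). That of Ctsg ended without IL-2 + LDHi replicate 2 (-7.77 to -6.05), and that of Prg2 without either IL-2 library, IL-21 + LDHi replicate 1 or IL-2 + LDHi replicate 2 (-9.79 to -2.56). Ak4 (5.18 to 6.51) and Gzma (-7.16 to -6.03) moved by more than 1.5-fold without IL-2 replicate 1, Gzmc (-8.57 to -5.995) without either IL-21 library, and Mpo (-8.25 to -7.01) without IL-2 + LDHi or IL-21 + LDHi replicate 2. So did Fam183b without any inhibitor or IL-21 library, Mgarp without replicate 1 of IL-21 or IL-21 + LDHi, Ctsg without either IL-2 + LDHi library and Prg2 without IL-2 replicate 2 or any inhibitor library. Among the fixed genes the calls of Ldhb (0.92 to 1.63) and Il7r (-1.06 to -0.71) ended without either IL-2 library, either IL-2 + LDHi library or IL-21 + LDHi replicate 2, that of Bcl6 (0.57 to 0.90) without any of these or IL-21 + LDHi replicate 1, that of Slc2a1 (0.91 to 1.75) without either IL-2 + LDHi library or IL-21 + LDHi replicate 2, and that of Prdm1 (-1.18 to -0.83) without IL-2 replicate 2 or any inhibitor library.

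For the interaction as a whole, overall scale of the libraries was weighed first. It would move all genes alike, but the median interaction of the CD8 T cell identity genes (-0.34) lay 3.45 above that of the G2 and M phase genes (-3.79). That argues against scale as the whole cause. The lists compared were picked with their values known. TMM scaling takes out a shift common to most genes, so such a shift could not be tested. IL-21 replicate 2 alone was weighed next: without it all 3124 genes kept the sign of their interaction, and 93.6% were called again. This cannot decide whether that library is the cause. The fit without it lacks the widest pair of replicates, so its spread is smaller and calls come back more easily. The 3124 genes were also chosen by a fit that holds both libraries. That the cytokine changes what the inhibitor does to division and effector genes of the T cells stays a hypothesis. Part of the interaction lies in genes of other blood cells, and differences in which cells were present may add to it, which stays open.

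Genes of other blood cells differed between conditions. A single mixture of such cells in different amounts would keep macrophage and basophil genes in 1 ratio, but the log2 ratio of 4 macrophage to 4 basophil genes differed between group means by up to 5.51 (2.88 in IL-2 + LDHi against -2.63 without cytokine) and between replicates by at most 0.79. That argues against 1 mixture in all 5 groups, and the gap comes from the inhibitor groups (2.88 and 1.97). Basophil genes near their floor there can only shrink that ratio. In the groups without inhibitor the ratios were -2.63, -1.45 in IL-2 and -2.30 in IL-21. No cytokine and IL-21 differ by 0.33, less than the replicates, so 1 mixture in different amounts may hold for them, and macrophage genes near their floor leave IL-2 open. Basophil or mast cell lineage cells, more in the cultures without cytokine, may be a source. For that lineage 9 further genes were chosen, without a check that they are particular to it. Their median was -4.67 in IL-2 against no cytokine and -3.12 in IL-21 + LDHi against IL-21, with Gata1 the exception in the latter. Mcpt8 measured 195 RPKM without cytokine and 43.4 RPKM in IL-21. The myeloid and dendritic list fell in the same comparisons (medians -4.12 and -1.45), so these falls do not single out basophils or mast cells. The CD8+ T cell isolation kit would remove such cells, and no cell count tests this.

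IL-21 replicate 2 stood apart from replicate 1, with an SD of the log2 difference of 0.805 against 0.519 in the next widest pair. Transcript length correlated with the difference across all genes with rho 0.258, the strongest of the pairs (-0.226 in IL-2 + LDHi, 0.152 without cytokine) but under the limit of 0.3, and over genes at 10 CPM or more with 0.301, against -0.395 in IL-2 + LDHi. With the length trend taken out of each pair the IL-21 SD was still 1.52 times the next, or 1.48 times over genes at 10 CPM or more, which argues against length as the whole cause. After thinning all libraries to 27126475 reads the IL-21 SD was still 1.52 times the next, and after the trend of the difference with GC content was taken out of each pair of replicates it was also 1.52 times (0.737), or 1.71 times over genes at 10 CPM or more, which argues against depth or a GC trend as the whole cause. GC content as a direction of the difference cannot be told apart, since rho was -0.488 against -0.479 in the pair without cytokine over all genes, but -0.64 against -0.72 over genes at 10 CPM or more. No biological explanation was tested, as the design names none within a group.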

How the results depend on the processing

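The longest transcript, the GC trend, and the list tests with 1 library left out or with library size alone were chosen after seeing the data; the other alternatives were chosen before. Of 19053 values of named genes under an alternative, 18156 kept their direction and side of the threshold, 805 kept the direction and lost the call, 59 gained a call and 33 changed sign, in 14 gene and comparison pairs. Of 883 called pairs 695 stayed called under every alternative that gave them a value. The stricter filter left some pairs without a value, and the minimum of 1.5-fold was not applied to named genes.

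With the stricter filter (8673 genes tested, so fewer calls by construction) 4484 genes were called for IL-2 against no cytokine, 1083 for IL-21, 4349 for IL-21 against IL-2, 3651 for the inhibitor in IL-2, 2563 for it in IL-21 and 1984 for the interaction. The cytokine responses then shared 307 higher and 318 lower genes, and the inhibitor responses 778 lower ones. A fit of only the groups compared takes the spread from those groups alone. Calls then fell to 105 for IL-21 against no cytokine, 4458 for IL-21 against IL-2 and 2162 for the inhibitor in IL-21. They rose without the IL-21 group, to 9101 for the inhibitor in IL-2, 7404 for IL-21 + LDHi against IL-2 + LDHi and 7468 for IL-2. The interaction, which includes IL-21, had 3229. The spread shared in the main fit may thus be too small for the IL-21 group, the widest pair, and its p values there too low. In these fits the cytokine overlap was 59 higher and 10 lower genes, and the inhibitor overlap 310 higher.

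With the GC trend taken out, IL-21 against no cytokine had 2707 calls (1622 of the 1658 kept), the cytokine overlap was 831 higher and 796 lower genes, and the inhibitor overlap 1201 higher. DESeq2 gave a cytokine overlap of 754 higher genes. By limma on log2(RPKM + 1) it was 231 higher and 860 lower, and the inhibitor overlap 831 lower. With a minimum of 1.5-fold the inhibitor overlap was 408 higher. With an estimated correlation 40 of the 109 list calls stayed. Fry called 151 lists, RLE 108, library size alone 113 and the replicate block 116, and 0 called lists turned direction. For these shifts the cause was not tested.

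Whether replicate numbers pair the libraries was checked on deviations from group means. Over 10 pairs of groups the correlation ran from -0.138 to 0.458, with 1 above 0.1 and 2 below -0.1, and the highest was between no cytokine and IL-21, which are compared directly. In these groups the difference between replicates (2 minus 1) also followed GC content alike (rho -0.479 without cytokine and -0.488 in IL-21). The other groups had rho from 0.197 to 0.253. Whether the GC trend makes up that highest correlation was not tested. The labels do not say what the replicate number stands for, so the replicate block stayed an alternative, with 7218 calls for IL-2 against no cytokine and 1616 for IL-21. Some genes of other cells went with the number, in a table made after seeing the data. The median of 12 B cell genes was lower in replicate 2 of all 5 groups (-0.98 without cytokine, -0.31 in IL-2, -1.11 in IL-21, -0.60 in IL-2 + LDHi, -2.21 in IL-21 + LDHi), and that of 4 basophil genes higher (1.19, 0.16, 0.56, 0.14 and 0.73). The median of the 4 macrophage genes plotted was also higher in replicate 2 of all 5 groups (0.43, 0.05, 0.2, 0.61 and 0.81). The fixed lists other than that of B cells did not follow the number in all groups. The 21 myeloid and dendritic genes had medians of 0.42, 0, 0.14, 0 and 0.05. Erythroid genes were higher in replicate 2 of 3 groups and lower in 2, and natural killer and CD4+ T cell genes higher in 1 and lower in 4. Whether libraries of 1 number share a cell isolation or another source stays open, and part of the spread between replicates lies in B cell, basophil and macrophage transcripts.

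Without 1 library, where the lone library is assumed to vary like the other groups, the calls ran from 5025 to 8779 for IL-2, 756 to 3921 for IL-21, 4592 to 8156 for IL-21 against IL-2, 3226 to 7264 for the inhibitor in IL-2, 2522 to 6517 for it in IL-21, 2098 to 5512 for IL-21 + LDHi against IL-2 + LDHi and 1780 to 5170 for the interaction. The cytokine overlap ran from 249 to 852 higher and 179 to 947 lower, and the inhibitor overlap from 327 to 1242 higher and 853 to 1640 lower.

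Among named genes, the sign of Ccr7 in IL-2 against no cytokine turned with RLE (0.020), DESeq2 (0.020), no filter (0.002), limma (0.031), the replicate block (0.010), the block with RLE (0.031) and the GC trend out (0.005), and that of Ccr7 in IL-21 against IL-2 with library size alone (0.021). With limma Pdcd1 in IL-21 against IL-2 was -0.110, Tcf7 for the inhibitor in IL-21 0.015, Il2ra in the interaction 0.008 and Prdm1 in the interaction 0.128. Tcf7 for the inhibitor in IL-21 was 0.009 with only those groups, and Ldhb in IL-21 + LDHi against IL-2 + LDHi 0.001 with the GC trend out. Prdm1 was the 1 of these that had been called. Without 1 library the ranges crossed 0 for Ccr7 with IL-2 (-0.219 to 0.251), with IL-21 (-0.411 to 0.242), between them (-0.407 to 0.246) and with the inhibitor in IL-2 (-0.010 to 0.145), Hk2 with IL-21 (-0.349 to 0.197) and in the interaction (-0.389 to 0.535), Ifng with the inhibitor in IL-2 (-0.064 to 0.313), Tcf7 with it in IL-21 (-0.055 to 0.011) and Pdcd1 in IL-21 against IL-2 (-0.319 to 0.377). They also did for Il2ra (-1.074 to 0.151) and Socs3 (-0.344 to 0.026) in the interaction, and for Ldhb (-0.187 to 0.153) and Slc2a1 (-0.174 to 0.047) in IL-21 + LDHi against IL-2 + LDHi. The cause was not tested.

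The share of calls that were higher moved with scaling: with library size alone from 50.8 to 40.9% for IL-2, from 48.9 to 37.2% for IL-21, from 45.2 to 56.3% for the inhibitor in IL-2 and from 36.7 to 25.3% for the interaction. That scaling shifts the median of all genes by -0.139, 0.118 and -0.14 for IL-2, the inhibitor in IL-2 and the interaction. By limma the share was 24.8% for IL-21, 30.9% for IL-21 against IL-2, 19.4% for IL-21 + LDHi against IL-2 + LDHi and 50.1% for the interaction, in which 9 calls had the other sign. In simulated data at the measured depth, with 2 libraries and the same spread in each group, 13.6% of genes changed 1.5-fold were called. That rate is for IL-21 + LDHi against IL-21, and the wider spread measured in IL-21 was not simulated. Depth was not varied on its own.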

Other observations

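The genes in the first paragraph were chosen after their values were seen, and the test in the second was planned before. Foxp3, a regulatory T cell factor, measured 4.10 ± 0.00463 RPKM (SD, n = 2) in IL-2 + LDHi and 0.860 ± 0.526 in IL-2. Its rise of 2.21 ± 0.40 (edgeR, adjusted p = 0.0025) became 3.04 without IL-2 replicate 2. Ncr1 and Klrb1c, receptors of natural killer cells, reached 4.12 ± 0.309 and 4.36 ± 0.240 RPKM in IL-2 + LDHi. Egr3, an early gene of receptor signalling, measured 3.39 RPKM in IL-21 and 0.150 in IL-21 + LDHi. Hspa1a, a heat shock gene, measured 0.0863 RPKM in IL-2 replicate 1 and 13.1 in replicate 2. Its change in IL-2 against no cytokine (7.80 ± 1.91) was 1.58 without replicate 2 and rests on that library. Cd79a, a B cell receptor gene, was higher in replicate 1 than in replicate 2 of each group, 4.48 against 0.518 RPKM without cytokine and 6.01 against 0.631 in IL-21 + LDHi.

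The inhibitor in IL-2 moved genes against the IL-2 response. A candidate explanation is a smaller IL-2 response, which leaves these cells nearer to those without cytokine. Of 4339 genes called in both comparisons 97.2% moved in opposite directions. The comparisons share the IL-2 libraries, with opposite signs, so a gene highest or lowest in IL-2 moves in opposite directions whatever the other group. The glycolysis median was -1.94 with the inhibitor in IL-2 and also -1.94 in IL-21 against IL-2, without inhibitor. Simulated sets sharing the IL-2 libraries had a mean covariance of -0.0816 against -1.43 measured, but held no IL-2 effect. Neither the share nor the covariance can thus decide for a smaller IL-2 response. Gzmb stayed above its level without cytokine, at 88.1 ± 6.62 RPKM against 17.8 ± 6.29. The inhibitor was present from activation onward, so the values cannot show a return from an IL-2 response that had already developed. Without a group that received the inhibitor and no cytokine, an effect of the inhibitor of its own on the same genes stays open.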
